A study of Macaca mulatta with 10 samples.

How the data were processed

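Expression was measured on Illumina HumanRef-8 v3.0 bead arrays, whose probes match human transcripts, with 1 array for each of 10 male rhesus macaques. Per the labels' protocols, total RNA was extracted from lymph node lysates with a column kit and DNase treatment, and biotin-labelled cRNA was made from it. The groups, stable and unstable social conditions with 5 animals each, and the replicate numbers were taken from the labels. The slide of each array was read from the labels, and 3 slides were used.

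The authors deposited a table of probe intensity values that were not normalized between arrays. GenomeStudio is named in the submitters' processing notes, with no version. The intensity table held 24526 probe identifiers without gene names, detection p-values or control probes, and its lowest values of 75.7 to 83.5 show no background subtraction. The authors also deposited a table of log2 values for 18622 gene symbols, which share nearly the same distribution across arrays, as quantile normalization gives. The normalization software and target distribution are not given in the sources used here. To match the tables, intensities were quantile normalized to a target distribution estimated from the authors' log2 values. That target lay a median of -0.068 log2 units from the one of the intensity table alone. The match gave 14854 gene rows equal to 1 probe within 0.002 log2 units on all 10 arrays. Another 1858 rows equalled the log2 of the mean of 2 probes within 0.008, which left 1910 rows unmatched. This match also gave probes their gene names. The correlation of matched rows was at least 0.999 with the same array and at most 0.9913 with any other. The same-array value follows from how these rows were chosen. Gene symbols are those of the authors' table and can be old. Of these, 12861 were found as symbols in a table of macaque genes, 552 only as synonyms, and 5209 were not found. No genome was given, so no coordinates are printed.

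The planned background correction and probe filter needed detection p-values, so the planned replacement was used: log2 intensity, quantile normalized, with all probes tested. Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene results used the authors' log2 table as deposited, with 1 row per symbol. The planned choice of the brightest probe per gene was not made, because probes are deposited without names and the match named only part of them. Human probes can bind macaque transcripts less well where the sequences differ, which lowers signals and can make a sequence difference between animals look like an expression difference. A probe was called above background on an array when it exceeded the mode of log2 signal by 3 SDs of the values below the mode. By this rule 8305 genes were above background on 3 or more arrays and 9205 on no array.

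Before the data were examined, 45 gene lists were fixed: the 3 parts of a social adversity signature, immune, stress and metabolic pathways, and markers of cell types in and around a lymph node. The 44 lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01, then with an estimated correlation and with fry. A list score is the mean log2 value over its measured genes, compared between groups with a two-sided exact permutation test over 252 regroupings, whose smallest p is 0.00794. Adjusted values of these tests cover 45 lists. Genes named in the text are the 10 with the smallest p in each direction, since none passed, a selection from the up to 3 genes of smallest p in a described list and up to 6 in each signature part, and a fixed set that includes NPY, TH and FKBP5, of which some genes are not reported here. Standard errors are those of limma's moderated fit.

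The limma fit was tested on simulated data with the spread of the 18622 genes and 5 simulations, in which 53 of 776 calls were false. Alternatives fixed at the same time as the lists were the gene table in place of the probe table, single-probe genes from the probe table, slide as a fixed or random block, slide 1 alone, age as a covariate, the 3 older unstable animals left out, the replicate number as a block, trend and robust eBayes, array weights, and each animal left out in turn. Alternatives added after the data were seen were normexp correction with an offset of 16 followed by quantile or median scaling, filters for signal above background on 3 or more or on all 10 arrays, and leaving out the pair of arrays with the lowest mean correlation to the others (stable 2 and unstable 4). Figures were drawn with matplotlib 3.10.9.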

Results

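Gene expression was measured in lymph nodes of 10 male rhesus macaques, 5 kept under stable and 5 under unstable social conditions. Each animal gave 1 array, so the replicates are separate animals. The arrays were Illumina bead arrays with probes designed on human transcripts, hybridised with labelled macaque RNA. The deposited values covered 24526 probes and, in a separate file, 18622 gene symbols. Median signal per array lay between 104 and 119, and 38.1% to 41.3% of probes were above background on an array. Correlations between arrays over the 8305 genes above background on 3 or more arrays ranged from 0.971 to 0.99. The number of arrays limits the precision, with a median standard error of 0.048 log2 units over all genes and 0.078 over the 8305 above background on 3 or more arrays. The stable animals 1 to 4 shared slide 2, stable animal 5 and unstable animals 1 to 3 shared slide 1, and unstable animals 4 and 5 shared slide 3. Only slide 1 therefore held both groups, with 1 stable animal on it. The age labels, whose unit is not stated, were 5.73 to 5.87 for the stable animals, 6.7 to 6.84 for unstable animals 1 to 3, and 5.61 and 5.62 for unstable animals 5 and 4. All unstable animals on slide 1 were thus the older ones, so values within slide 1 do not separate social condition from age label. Fits without the older animals keep unstable animals on slide 3 only, where no stable animal was. Those fits do not separate social condition from slide.

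The series asks whether lymph node expression differs between unstable and stable social conditions. No gene passed the adjusted threshold. The gene with the smallest p was LRRC41, which encodes a leucine-rich repeat protein, at 8.18 ± 0.033 (SD, n = 5) in stable and 7.97 ± 0.029 (SD, n = 5) in unstable animals on the log2 scale (limma adjusted p = 0.42). Every stable animal was above every unstable animal for LRRC41. TOM1, an endosomal trafficking adaptor, had a log2 difference of -0.20 (SE 0.031), and GSDMDC1, the older symbol of gasdermin D, the pore-forming protein of pyroptosis, had one of -0.35 (SE 0.055), each with a limma adjusted p of 0.468. Of the genes with higher means in unstable animals, ATP6V0E1, a subunit of the vacuolar proton pump, had the smallest p, with 12.50 ± 0.075 (SD, n = 5) in stable and 12.73 ± 0.069 (SD, n = 5) in unstable animals (limma adjusted p = 0.83).

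Another 7 genes made up the 10 with the smallest p among those with lower means in unstable animals. PTPRCAP, which binds the CD45 phosphatase, differed by -0.33 (SE 0.064), and LAT2, a membrane adaptor of B cells and mast cells, by -0.19 (SE 0.037). The casein kinase CSNK1G2 differed by -0.43 (SE 0.079) and LGALS3BP, a secreted galectin-binding glycoprotein, by -0.40 (SE 0.087). C11orf2, MGC52498 and ACTG1 differed by -0.29, -0.52 and -0.23, with ACTG1 above background on 5 arrays. The differences of C11orf2, MGC52498, ACTG1, LAT2 and GSDMDC1 within slide 1 were smaller, at -0.187, -0.291, -0.088, -0.077 and -0.189, while with normexp correction and quantile scaling C11orf2, MGC52498, ACTG1 and LGALS3BP were larger, at -0.47, -0.779, -0.585 and -0.756. Among the genes with higher means, TBC1D7, a partner of the TSC complex, differed by 0.22 (SE 0.045), CKS1B, a regulator of cyclin-dependent kinases, by 0.19 (SE 0.04), and the kinase PDPK1 by 0.15 (SE 0.033). HECW1, TFCP2, UPF3A, FLJ22104, PCSK1N and UBE2G1 differed by 0.12 to 0.30, with HECW1 above background on 1 array. PCSK1N moved from 0.25 to 0.16 within slide 1 and 0.52 with normexp and quantile, HECW1 to 0.344 with the latter, and TFCP2 and FLJ22104 to 0.412 and 0.476 with normexp and median scaling. None of these genes passed, with limma adjusted p from 0.83 to 0.892.

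Over all 24526 probes, limma put 0 past an adjusted p of 0.05, with 0.712 the smallest adjusted p. At an unadjusted p under 0.05 there were 1262 probes, 610 higher and 652 lower in unstable animals, where 1226 are expected by chance. The groups did not overlap for 220 probes, where chance gives 0.794% or 195 probes. At the level of genes, 0 of 18622 passed and 956 had an unadjusted p under 0.05, against 931 expected. In simulated data of the same spread, limma recovered 25.6% of genes shifted by 0.25 log2 units, 71.2% of those shifted by 0.5 and 93.2% of those shifted by 1. Those simulations had independent genes and no slide effect, and shifted many genes above background at once, by up to 2 log2 units. Many true changes ease the adjusted threshold, so these shares do not hold for a few changed genes. With slide as a block, 1 probe of MRPL38 passed (limma adjusted p = 0.0385), and without the 3 older unstable animals 1 probe of HSBP1 passed (limma adjusted p = 2.09e-05), both named after their values were seen. HSBP1 stood at 6.85 and 7.08 in unstable animals 1 and 2, at 9.23, 9.02 and 8.87 in unstable animals 3, 4 and 5, and at 6.89 to 6.99 in the stable animals, so that the fit without the older animals set 2 unstable animals against 5 stable ones.

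**Figure D1:**
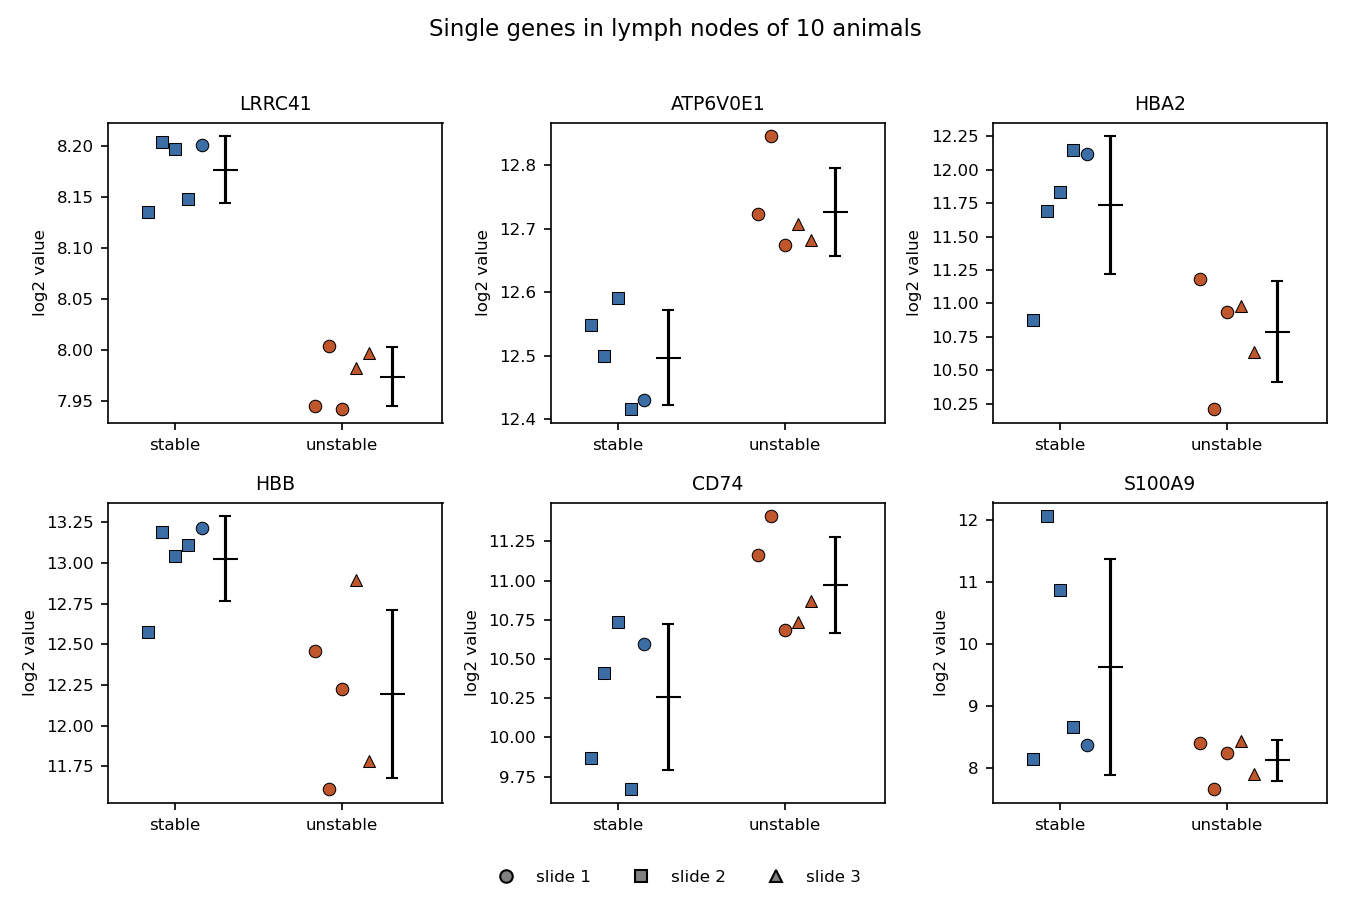
Log2 expression of 6 genes in each of 10 animals, with stable animals on the left and unstable animals on the right of each panel, slides shown by marker shape, and the bar giving the mean ± SD of 5 animals. LRRC41 and ATP6V0E1 separate the groups with differences of -0.20 and 0.23, HBA2, HBB and CD74 overlap between groups, and S100A9 is set apart by 2 stable animals; none passed the adjusted threshold over all genes.

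Genes of MHC class I presentation and interferon response were lower in unstable animals as groups. Of 19 measured genes of MHC class I presentation, which loads peptides for CD8 T cells, 18 had lower means, and the list passed limma's camera test with a preset correlation (adjusted p = 0.00095; adjusted p = 0.763 with an estimated correlation). The list's mean log2 value was 9.68 ± 0.092 (SD, n = 5) in stable and 9.54 ± 0.087 (SD, n = 5) in unstable animals, a difference of -0.14 (exact permutation p = 0.0476, adjusted 0.714). HLA-E, a ligand of NK cell receptors, differed by -0.26 (SE 0.093), the peptide transporter TAP1 by -0.15 (SE 0.059), and the chaperone CALR by -0.29 (SE 0.115), and none of them passed on its own. CALR differed by -0.167 without stable animal 2 and by -0.191 within slide 1, and HLA-E by -0.044 within slide 1. The difference of this list within slide 1 was 0.039, in the opposite direction, and without the older animals it was -0.218.

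Of 45 measured interferon-stimulated genes 31 had lower means, and the list passed camera (adjusted p = 0.00841; adjusted p = 0.763 with an estimated correlation), with a mean shift of -0.086. ISG20, an exonuclease acting on viral RNA, differed by -0.32 (SE 0.102), TRIM22 by -0.23 (SE 0.09) and IRF7, the factor that drives type I interferon transcription, by -0.16 (SE 0.058). IRF7 was above background on 3 arrays. Without stable animal 3 the shift was -0.027 and TRIM22 differed by -0.149, and the list no longer passed. Within slide 1 the shift was -0.037, with ISG20 at -0.148 and IRF7 at -0.08, without the older animals it was -0.033 and the list did not pass, and with normexp and quantile it was -0.137. Of 19 interferon-gamma induced genes 15 had lower means, IRF1 among them at -0.17 (SE 0.057), and the list passed camera (adjusted p = 0.0311; adjusted p = 0.763 with an estimated correlation). Within slide 1 its shift was -0.069, against -0.087 over all slides, and it passed in 5 of 10 fits with 1 animal left out, with shifts from -0.051 without stable animal 2 to -0.135 without unstable animal 5. Without the older animals the list's shift was -0.002 and it did not pass. IRF1 was at -0.07 in that fit, at -0.099 with age as a covariate, and at -0.286 within slide 1.

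Plasma cell genes and ribosomal protein genes also had lower means as groups, again called only by camera at its preset correlation. Of 15 measured plasma cell genes 12 had lower means, with SSR4, a subunit of the translocon-associated complex, at -0.21 (SE 0.068), and the list passed camera (adjusted p = 0.0255; adjusted p = 0.763 with an estimated correlation). Its shift was -0.087 over all slides, -0.022 within slide 1, where SSR4 was at -0.134, -0.031 without stable animal 3 and -0.131 without stable animal 1, and the call ended without stable animal 2, stable animal 3 or unstable animal 5. Of 73 ribosomal protein genes 45 had lower means, with a mean shift of -0.028, and the list passed camera (adjusted p = 0.0255; adjusted p = 0.836 with an estimated correlation). RPL31 differed by -0.22 (SE 0.054) and RPS24 by -0.18 (SE 0.052). The ribosomal shift within slide 1 was -0.02 and RPL31 stood at -0.07, without the older animals the shift was -0.083, and the list passed in 4 of 10 fits with 1 animal left out, with shifts from -0.052 without stable animal 4 to -0.013 without unstable animal 4.

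Cell cycle, oxidative phosphorylation and cytotoxic lymphocyte genes had higher means in unstable animals as groups, called only by camera at its preset correlation of 0.01. The estimated correlation between genes was 0.518 for cell cycle, 0.296 for oxidative phosphorylation, 0.174 for cytolytic genes and 0.054 for CD8 T and NK cell markers. Of 44 measured cell cycle genes 37 had higher means, 6 of them with an unadjusted p under 0.05, and the list passed camera (adjusted p = 2.94e-07; adjusted p = 0.827 with an estimated correlation). HMGB2, a chromatin protein of dividing cells, differed by 0.17 (SE 0.049), the tubulin regulator STMN1 by 0.099 (SE 0.031) and RRM1, a subunit of ribonucleotide reductase, by 0.21 (SE 0.076). STMN1 was above background on 3 arrays. The list's mean log2 value was 7.61 ± 0.06 (SD, n = 5) in stable and 7.74 ± 0.197 (SD, n = 5) in unstable animals (exact permutation p = 0.214), and within slide 1 the difference was 0.025, with HMGB2 at 0.049, STMN1 at 0.035 and RRM1 at 0.132. The list passed with any 1 animal left out, at a shift of 0.067 without unstable animal 5, at 0.267 without the older animals, and at 0.196 over genes above background on all 10 arrays. Its mean was 7.60 and 7.49 in unstable animals 1 and 2, against 7.54 to 7.69 in the stable animals. It was 7.85, 7.76 and 7.99 in unstable animals 3, 4 and 5. Leaving out 1 animal cannot reveal a shift carried by several, so these fits do not show a shift shared by all unstable animals. With normexp and median scaling HMGB2 was at 0.411. Germinal centre markers, 11 of 12 with higher means, did not pass camera (adjusted p = 0.127), and both lists were lowest in unstable animal 2 among the unstable animals. Cytolytic genes were higher in 10 of 13 cases, and the list passed camera (adjusted p = 0.0311; adjusted p = 0.763 with an estimated correlation), as did the markers of CD8 T and NK cells, 18 of 26 higher (adjusted p = 0.0442; adjusted p = 0.763 with an estimated correlation). GNLY, the antimicrobial protein granulysin, differed by 0.39 (SE 0.141), the protease GZMK by 0.44 (SE 0.211) and the receptor KLRB1 by 0.20 (SE 0.065). KLRB1 was above background on 5 arrays. Within slide 1 the cytolytic shift was 0.29, that of CD8 T and NK cell markers 0.13, GNLY 0.705 and GZMK 0.996; GZMK was 0.291 without unstable animal 2, and KLRB1 was 0.528 with normexp and median scaling. Without the older animals the shift was 0.039 for CD8 T and NK cell markers and 0.084 for cytolytic genes, and neither list passed. GNLY differed by 0.245 and KLRB1 by 0.126 in that fit. Over genes above background on 3 or more arrays the shift of CD8 T and NK cell markers was 0.117 (camera adjusted p = 0.00563). With 1 animal left out the cytolytic list passed in 3 of 10 fits, at a shift of 0.059 without unstable animal 2 and 0.073 without stable animal 5, and the CD8 T and NK list in 4 of 10, at 0.05 to 0.085. Of 38 oxidative phosphorylation genes 29 had higher means, ATP5A1 among them at 0.24 (SE 0.11) while COX6C stood at -0.21 (SE 0.095), and the list passed camera (adjusted p = 0.0255; adjusted p = 0.956 with an estimated correlation). Without unstable animal 4 its shift was -0.007 and ATP5A1 differed by 0.127, within slide 1 these were -0.002 and 0.073, and without the older animals they were 0.207 and 0.399. The list passed in 7 of 10 fits with 1 animal left out. The call ended without stable animal 3, stable animal 4 or unstable animal 4, and with normexp and quantile (camera adjusted p = 0.0747). Adipocyte markers stood at 8.24 in unstable animal 4 and at 7.17 to 7.49 in the other 4 unstable animals, and that list did not pass camera (adjusted p = 0.377).

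In all, 11 of 44 lists with at least 5 measured genes passed camera, 7 lower and 4 higher in unstable animals. Some of these lists share genes. GNLY and GZMK were in the cytolytic and the CD8 T and NK lists, and TAP1 in the MHC class I and interferon-gamma lists. IRF7 was in the interferon-stimulated and type I interferon lists, so the calls of such lists are not independent. With an estimated correlation 0 lists passed (1 with an unadjusted p under 0.05), and 0 passed limma's fry test, whose smallest adjusted p was 0.812. With slide as a fixed block 0 lists passed, in a fit whose group difference rests on slide 1 and its 1 stable animal. With slide as a random block 9 passed at the preset correlation, all of them among the 11. Here camera was run on the moderated t values of that fit. The estimated correlation within slides was -0.084 over probes. A value below 0 allows for no likeness within slides, so this fit does not show that the calls hold after allowing for slide. The fit without stable animal 3 passed 4 lists.

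**Figure D2:**
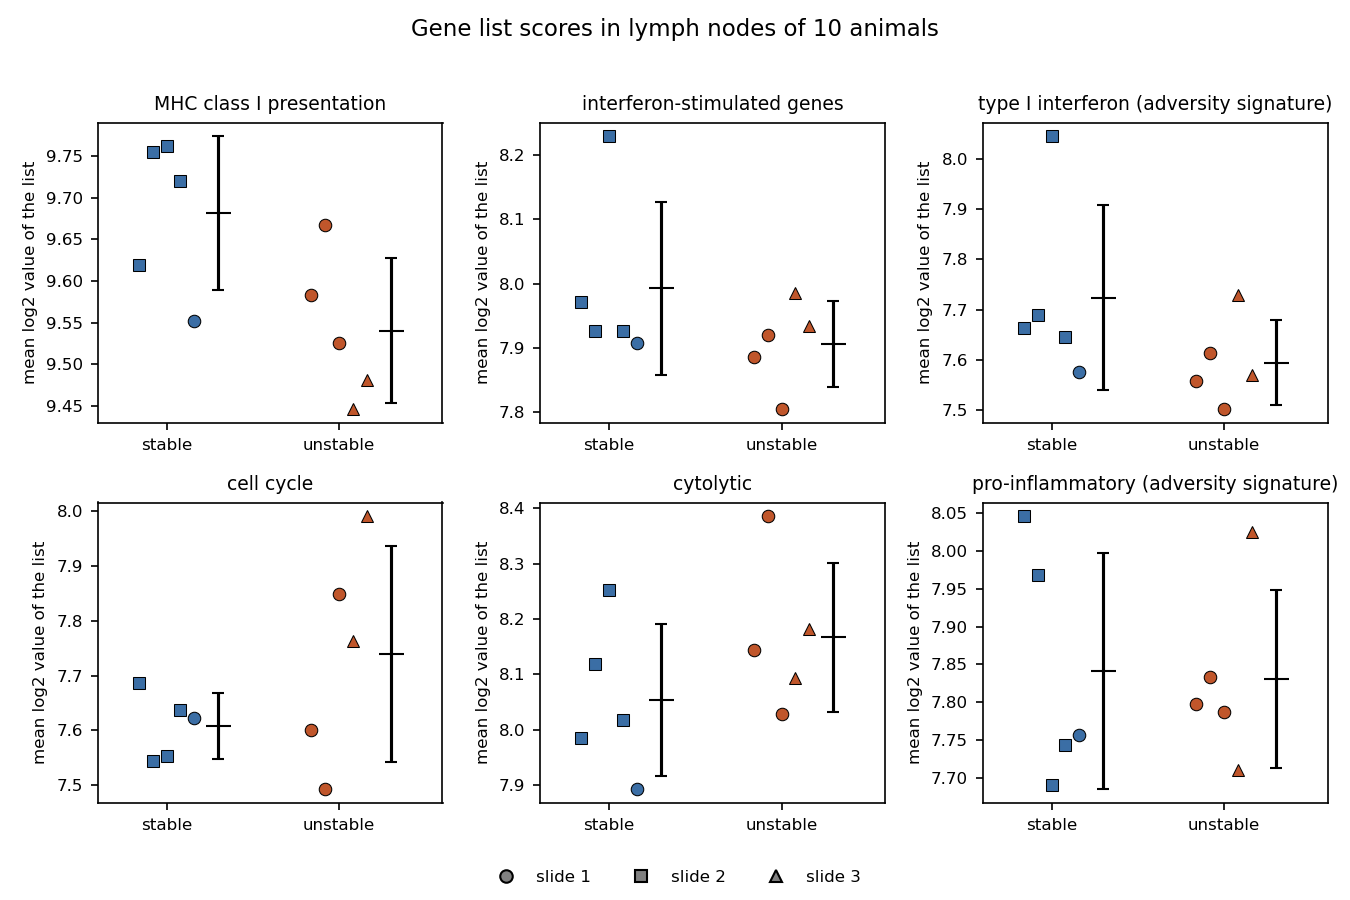
Mean log2 value of 6 gene lists in each of 10 animals, with stable animals on the left and unstable animals on the right of each panel, slides shown by marker shape, and the bar giving the mean ± SD of 5 animals. The MHC class I list differs by -0.14 between groups, stable animal 3 stands at 8.23 for the interferon-stimulated list, and the pro-inflammatory list differs by -0.01.

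The erythroid list was lower in lymph nodes of unstable animals, with its largest differences in a pair of globin genes. HBA2, an alpha globin gene, was at 11.73 ± 0.516 (SD, n = 5) in stable and 10.79 ± 0.378 (SD, n = 5) in unstable animals, a difference of -0.94 (SE 0.251), and HBB, the beta globin gene, differed by -0.83 (SE 0.228). Within slide 1 these differences were -1.34 and -1.12. Neither passed over all genes (limma adjusted p = 0.918), and both passed adjusted over the list alone (0.0354). They were the only 2 genes of the 45 lists to do so. That adjustment takes no account of the number of lists, so a pass in 1 of 45 lists can come from chance alone. The erythroid list, with 14 of 17 genes lower, passed camera (adjusted p = 0.0265; adjusted p = 0.763 with an estimated correlation), with a shift of -0.11, and of -0.15 within slide 1. The erythroid list passed in 4 of 10 fits with 1 animal left out, did not pass without the older animals (-0.089, camera adjusted p = 0.134), and had a shift of -0.196 with normexp and quantile. Only 5 of its genes were above background on 3 or more arrays, and the other 3 of these, HBD, ERAF and SELENBP1, differed by -0.097 (SE 0.06), -0.001 (SE 0.104) and 0.47 (SE 0.313), named after their values were seen. With these 5 genes alone the shift was -0.282 and the list did not pass camera (adjusted p = 0.0555). SELENBP1 differed by 0.14 without unstable animal 4 and 0.784 without the older animals, and HBD by -0.057 without stable animal 5, -0.279 within slide 1 and -0.25 with normexp and quantile. Platelet genes, 3 of 14 above background, had a shift of 0.013 (camera adjusted p = 0.982). Neutrophil genes had a list mean of 7.17 ± 0.146 (SD, n = 5) in stable and 7.03 ± 0.019 (SD, n = 5) in unstable animals (exact permutation p = 0.0159, adjusted 0.358), and the list did not pass camera (adjusted p = 0.227). Its shift of -0.141 was -0.08 without stable animal 2, which stood at 7.42 against 7.04 to 7.19 in the other stable animals, and -0.315 over the 9 of 23 genes above background on 3 or more arrays (camera adjusted p = 0.0555). S100A9, a calcium-binding protein of neutrophils and monocytes, differed by -1.49 (SE 0.692), the growth factor receptor CSF3R by -0.41 (SE 0.15) and the antimicrobial peptide gene CAMP by -0.57 (SE 0.278). The S100A9 difference came with values of 12.06 and 10.86 in stable animals 2 and 3, and between 7.67 and 8.66 in the other 8 animals. Without stable animal 2 S100A9 differed by -0.884 and CAMP by -0.306. The neutrophil shift within slide 1 was -0.077, S100A9 differed by -0.28, CSF3R by -0.084 and CAMP by 0.054.

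A published social adversity signature holds 19 pro-inflammatory genes, 31 type I interferon genes and 3 antibody genes, and the question was whether these lists shift between the conditions. All 19 pro-inflammatory genes were measured, 6 with higher and 13 with lower means. Their mean log2 value was 7.84 ± 0.156 (SD, n = 5) in stable and 7.83 ± 0.118 (SD, n = 5) in unstable animals, a difference of -0.01 (exact permutation p = 0.944), and of 0.049 within slide 1. The transcription factor gene NFKB2 differed by -0.12 (SE 0.064), the cytokine IL1B by -0.094 (SE 0.085) and JUN by 0.24 (SE 0.299). IL1B, above background on 1 array, differed by -0.016 without stable animal 2 and -0.242 with normexp and quantile, and JUN by 0.017 without unstable animal 5, 0.477 without stable animal 1, 0.39 within slide 1 and 0.514 without the older animals. Of 29 measured type I interferon genes 21 had lower means, and the list passed camera (adjusted p = 0.0265; adjusted p = 0.763 with an estimated correlation). Its mean log2 value was 7.72 ± 0.185 (SD, n = 5) in stable and 7.59 ± 0.085 (SD, n = 5) in unstable animals. The difference of -0.13 did not pass the exact permutation test (p = 0.167). The difference was -0.049 without stable animal 3, -0.018 within slide 1 and -0.074 without the older animals, where the list did not pass. It was -0.202 over genes above background on 3 or more arrays, and the list passed camera in 5 of 10 fits with 1 animal left out. IFI30, a lysosomal thiol reductase, differed by -0.43 (SE 0.137) and the antiviral GTPase MX1 by -0.46 (SE 0.235), and within slide 1 these were 0.12 and 0.044. MX1 differed by -0.237 without stable animal 3 and -0.689 with normexp and quantile. The antibody genes IGLL1 and IGJ, the only 2 measured, differed by -0.095 (SE 0.051) and 0.056 (SE 0.234), or, for IGLL1, by -0.061 without stable animal 3 and -0.04 within slide 1, and, for IGJ, by -0.071 without stable animal 4 and 0.245 without stable animal 2. The contrast of the 3 lists over 50 genes, in standard deviations per gene with the sign turned for interferon and antibody genes, was -0.07 ± 0.368 (SD, n = 5) in stable and 0.07 ± 0.223 (SD, n = 5) in unstable animals (exact permutation p = 0.587). The difference of 0.14 was -0.023 without stable animal 3, 0.062 without unstable animal 5, 0.218 without unstable animal 4, -0.017 with slide as a block, and 0.03 when genes were standardized over slide 1 alone. It was 0.271 over genes above background on 3 or more arrays, 0.253 over those above it on all 10, and 0.234 without stable animal 2 and unstable animal 4.

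No gene or list described here for stress hormone response or sympathetic innervation passed its test. FKBP5, a glucocorticoid-induced regulator of the glucocorticoid receptor, was at 8.08 ± 0.278 (SD, n = 5) in stable and 7.93 ± 0.141 (SD, n = 5) in unstable animals, a difference of -0.16 (SE 0.124; limma adjusted p = 0.95), of -0.036 without stable animal 2, of 0.12 within slide 1, and of -0.294 without the older animals. Of 28 measured glucocorticoid-induced genes 14 had higher and 14 lower means, with a mean shift of -0.022 (camera adjusted p = 0.979, in the upward direction). NPY and TH, markers of sympathetic nerves, were above background on 0 of 10 arrays, so their differences of -0.001 and 0.017 compare values at background. The 28 measured genes of cAMP and adrenergic response were split into 13 with higher and 15 with lower means (camera adjusted p = 0.979). Of 29 neurotrophin and sympathetic nerve genes 19 had higher means (camera adjusted p = 0.613). Only 8 of these 29 genes were above background on 3 or more arrays, so this list cannot decide whether innervation differed.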

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

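The fits within slide 1 and without 1 animal were planned, but what they had to show in the tests of a single animal and of slide was set after the result was seen, while the tests of age and blood content were set before it. In 214 groups of 5 values tested, 20 had 1 animal far from the other 4, where chance alone gives about 10.7.

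Stable animal 3 stood apart from the other stable animals for the type I interferon list (8.05 against 7.58 to 7.69), the interferon-stimulated list (8.23 against 7.91 to 7.97) and the adversity signature contrast (-0.72 against 0.02 to 0.13). Without this animal the lower interferon-stimulated list in unstable animals moved from -0.086 to -0.027 and its call ended, so the shift may rest largely on 1 animal. Slide cannot be told apart from social condition here, since the shift within slide 1 was -0.037 with 1 stable animal there. Without the 3 unstable animals of higher age label the shift was -0.033, which leaves age open as well. The unstable animals left in that fit were on a slide without stable animals, so it does not separate age from slide. The social condition itself stays open as an untested explanation.

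Stable animal 1 had lower values than the other stable animals for HBB (12.58 against 13.04 to 13.22) and the erythroid list (7.34 against 7.46 to 7.49). The mean of HBA2 and HBB was 12.38 ± 0.38 (SD, n = 5) in stable and 11.49 ± 0.43 (SD, n = 5) in unstable animals, a difference of -0.89 (exact permutation p = 0.0238, for a pair of genes picked after seeing them). Less blood in the tissue of unstable animals would also lower neutrophil and platelet transcripts, whose lists shifted by -0.141 (-0.08 without stable animal 2; 9 of 23 genes above background) and 0.013 (3 of 14 above background), and across 10 animals the neutrophil and globin deviations from the group means correlated at r = 0.16 (permutation p = 0.667; Spearman's rho = 0.02, permutation p = 0.972), or -0.43 without the 2 animals farthest out. This r lay under the bound of 0.2 set beforehand as evidence against blood content, but by less than its jackknife standard error of 0.34, a comparison made after r was seen, so blood content stays open. Within slide 1 the difference was -1.23, but with 1 stable animal there slide cannot be told apart from social condition.

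Other animals stood apart in single measures. Unstable animal 4 was highest of its group for the oxidative phosphorylation list (9.99 against 9.53 to 9.57), ATP5A1 (12.02 against 11.36 to 11.55), the lipid and cholesterol synthesis list (7.48 against 7.16 to 7.22), the platelet list (6.99 against 6.88 to 6.92), MX1 (7.83 against 7.18 to 7.29) and SELENBP1 (9.54 against 7.58 to 8.13). Stable animal 2 was highest for CALR (9.50 against 8.85 to 8.95), IL1B (7.15 against 6.70 to 6.79) and FKBP5 (8.57 against 7.90 to 8.02). FLJ22104 was highest in stable animal 3 (8.07 against 7.69 to 7.77). The lymphoid chemokine and organisation list (8.82 against 8.75 to 8.76) and CFB, a complement factor (7.44 against 7.16 to 7.22), were highest in unstable animal 1, IFI30 in unstable animal 2 (10.33 against 10 to 10.07) and GNLY in unstable animal 3 (8.10 against 7.58 to 7.70). TH was lowest in unstable animal 3 (6.66 against 6.72 to 6.73).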

How the results depend on the processing

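Fits with normexp, filters for signal above background, or without stable 2 and unstable 4 were added after the data were seen. The planned filters on detection p and the planned neqc correction with median scaling were not run, since they need detection p-values. No probe passed in 12 of 14 settings or with any animal left out (1090 to 1407 probes at an unadjusted p under 0.05). The exceptions were 1 probe with slide as a fixed block (MRPL38, adjusted p = 0.0385), where stable animal 5 alone stood at 7.96, and 1 without the 3 older unstable animals (HSBP1, adjusted p = 2.09e-05), both named after their values were seen. Over the settings the smallest adjusted p ranged from 2.09e-05 to 0.986. Camera passed 11 lists; other settings passed 7 with single-probe genes (6 of them among the 11), 6 with normexp and quantile (5 among the 11), 7 of 34 lists with genes above background on all 10 arrays (all 7), 0 with slide as a fixed block, 3 within slide 1 (1), 6 with age as a covariate (5), 8 without the older animals (5), 7 without stable 2 and unstable 4 (all 7), 0 with an estimated correlation and 0 with fry. Slide as a random block gave 9 lists, all 9 among the 11. It gave 1862 probes at an unadjusted p under 0.05, against 1262 in the main fit. Its estimated correlation within slides was -0.084 over probes, so it allowed for no likeness within slides. Leaving out 1 animal gave 4 to 10 lists, 4 to 9 of them among the 11: 4 without stable 3, 5 without stable 2 or unstable 5, and 7 without stable 4 or unstable 1. The replicate block gave 0 probes (1223 at an unadjusted p under 0.05) and 11 lists; same-numbered animals had deviation correlations of -0.06 to 0.01 and 0 stable animals correlated best with their own number, so the numbers do not pair the animals.

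The pro-inflammatory difference of -0.01 was 0.023 with genes above background on all 10 arrays, 0.049 with slide as a block and within slide 1, 0.008 with age, 0.027 without the older animals, 0.052 without stable 2 and unstable 4, and -0.059 to 0.041 with 1 animal left out. The signature contrast of 0.14 was -0.017 with slide as a block, 0.271 and 0.253 with genes above background on 3 or more and on all 10 arrays, 0.234 without stable 2 and unstable 4, and -0.023 to 0.218 with 1 animal left out. The type I interferon difference stayed below 0 in every setting run, from -0.202 to -0.018. With slide as a block and within slide 1, the MHC class I list was 0.039, oxidative phosphorylation -0.002 (and -0.007 to 0.108 with 1 animal left out), IFI30 0.115, MX1 0.044, TH -0.007, FKBP5 0.118, CAMP 0.054 and ERAF 0.018. NPY was 0.001 with slide as a random block, 0.05 with age and 0.065 without the older animals. IGJ was -0.098 with age and -0.187 without the older animals. Without stable 2 and unstable 4, FKBP5 was 0.01 and ERAF 0.002; ERAF was also 0.002 with slide as a random block and 0.006 with array weights. With 1 animal left out IGJ ran from -0.071 to 0.245, NPY from -0.024 to 0.032, ERAF from -0.097 to 0.053 and TH from -0.005 to 0.043. The cause of these changes was not tested, apart from there being fewer animals or genes in some fits. Of 1402 values of 61 genes under the alternatives, 1366 kept their direction and 0 passed the adjusted threshold. Signal over background is the other limit: 9205 genes were above background on no array.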

Other observations

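Among genes of MHC class II presentation, which shows peptides to CD4 T cells, CD74, the invariant chain, was at 10.25 ± 0.465 (SD, n = 5) in stable and 10.97 ± 0.308 (SD, n = 5) in unstable animals, a difference of 0.72 (SE 0.219; limma adjusted p = 0.918), while 11 of the 19 measured genes of the list had lower means (mean shift 0.032, median -0.065) and the list did not pass camera (adjusted p = 0.982). In the complement list the groups did not overlap for CFB, with a difference of -0.45 (SE 0.115; limma adjusted p = 0.892). PPP1R15A, a stress-induced phosphatase subunit among the immediate early genes, differed by -1.09 (SE 0.341; limma adjusted p = 0.918). Markers of Schwann cells, the glia of peripheral nerves, had a list mean of 7.08 ± 0.01 (SD, n = 5) in stable and 7.11 ± 0.014 (SD, n = 5) in unstable animals (exact permutation p = 0.0159, adjusted 0.358), with GFRA3 at 0.45 (SE 0.15) and CDH19, above background on 0 arrays, at 0.091 (SE 0.03). This list did not pass camera (adjusted p = 0.29, or 0.763 with an estimated correlation), and 5 of its 15 genes were above background on 3 or more arrays. Its shift of 0.033 was 0.062 over those 5 genes (camera adjusted p = 0.762), but over the 7 genes read from a single probe it was 0.102 (camera adjusted p = 0.031), and over the 7 after normexp 0.221 with quantile (camera adjusted p = 0.0188) and 0.207 with median scaling (camera adjusted p = 0.043), so the list passed in 3 settings. These 3 calls used camera's preset correlation only. Within slide 1 GFRA3 differed by 0.241 and CFB by -0.173, and with normexp and quantile they differed by 0.815 and -0.734 and CDH19 by 0.337.

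B cell markers had 16 of 20 genes with lower means (camera adjusted p = 0.3), T cell markers 15 of 22 (camera adjusted p = 0.698) and macrophage and monocyte markers 23 of 33 (camera adjusted p = 0.377).

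Other splits of the 10 arrays into 5 and 5 were counted, 100 of 126 with the real one included. For the 0 probes past the adjusted threshold the count says nothing, since all 100 splits must give at least 0, and the highest of the other splits gave 1. As many probes as the 1262 at an unadjusted p under 0.05 came from 28 splits, with 1711 the highest other. As many lists as the 11 past camera came from 13 splits, with 17 the highest other. Chance cannot be excluded for either of these last counts.

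On 26 probes the animals fell into sets over 1 log2 unit apart with at least 2 animals on each side, where normal noise of the same SD gave at most 14 in 20 simulations, and on 0 of them did the sets match the social groups. S100A9, PPP1R15A, HLA-G, HSBP1, HLA-DRB5 and HLA-DPB1 were among them, with HLA-DRB5 showing the largest gap, at 4.07. HLA-G stood at 9.71 in stable animal 1 and at 9.28 and 8.85 in unstable animals 4 and 5, against 10.86 to 11.70 in the others. All of these but S100A9 and PPP1R15A were named after their values were seen, as are HNRPC and RPL9 below. If a sequence difference under the human probe were the cause, a second probe of the same gene would not show the split. Only 2 such probes had a partner above background on all 10 arrays, for HNRPC and RPL9, and the partners' median SD was 0.15 against 0.92, a ratio of 0.16. The 1120 other probes above background in 2-probe genes had a median SD of 0.14, so any partner of usual spread gives such a ratio. The partners did not follow the split (r = 0 and -0.1), so it was confined to 1 probe in these 2 genes. A sequence difference would give this, but so would any other cause acting on 1 probe alone. The other probes stay untested.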
